A study of Homo sapiens with 14 samples.

How the data were processed

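RNA immunoprecipitation sequencing (RIP-seq) was carried out in 293FT cells, an established human embryonic kidney line. Per the labels' protocols, cells in 15 cm dishes received 25 µg of plasmid, were collected 3 days later and were fixed with 0.3% formaldehyde for 10 minutes. Lysates in 150 mM NaCl were sonicated and incubated with IgG or a FLAG antibody, and beads were washed in 1 M NaCl before RNA was eluted. The 14 samples comprised 7 RIP libraries and 7 inputs, and each group was 1 library. A peak list was used for each of the 7 RIP libraries; values of the inputs were not analysed here.

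Reads were aligned and peaks called with HISAT2 and MACS2 on hg38, per the submitters' processing notes, which name these tools and the build without versions. The caller's settings, the threshold and the use of each input as control are not given in the sources used here. Each deposited list holds 1 row per peak, and in every row the start and end lie 1 base apart, so a peak is a position without a width. Peak names in the deposited lists mark the plus or minus strand of the reads, called separately. The last column of the deposited lists is a whole number that the authors did not name; it is called the authors' score here, and its lowest value was 2 in each list. The score was used to rank or filter peaks within a list and is not compared between lists. Read totals are not part of a peak list, so the depth of each library is unknown, and a longer list can come from more reads, another threshold or more bound RNA.

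Coordinates are 1-based positions on hg38. A table of 59716 RefSeq genes on the same build gave gene names, biotypes and spans, without exons, gene strands or sequence. A peak was assigned to a small noncoding RNA gene where its position lay in the span of exactly 1, was left unassigned where several small RNA spans or a pseudogene span covered it, and otherwise went to a protein-coding or lncRNA gene where exactly 1 such span covered it. Near-identical gene copies, as in the histone and ribosomal RNA clusters, can share reads, so the member named at such a site is uncertain. The planned split into coding sequence, untranslated regions and introns, the base composition and the matching on exon length need exons or sequence and were not run; gene span replaced exon length, and the position along the span replaced the region. The strand of the reads was checked against the known strand of a set of genes, and 274 of 275 peaks in 20 of them lay on the strand opposite to the gene. The direction of transcription was therefore taken as opposite to the read strand.

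Peaks of different lists counted as shared where they lay on the same strand within 100 bases. This window was chosen after the lists were seen to hold positions; the overlap of 1 base planned for intervals became the alternative of an identical position. Peaks of a Cas list within 100 bases of a peak in either vector list were removed before the Cas lists were compared. Overlaps were set beside 1000 random placements of the gene-assigned peaks within the merged regions, 100 bases either side of any Cas peak, of the same gene, and beside 100 placements in the whole gene span. For 16 gene lists fixed before the data were examined, the members with a peak were set beside 10000 random lists of the same size. These were drawn from the 6637 genes with a peak in any list and matched on deciles of span. Members without a peak in any list were left out of the counts, so shares of members are not shares of whole gene lists. Placements and random lists describe these libraries and are not tests between conditions. Random lists were not matched on RNA abundance, which was not measured here, so a call above the range can follow abundant RNA. Shares carry exact Clopper-Pearson 95% intervals and ratios of counts the intervals derived from them; these cover counting error only. The planned difference of scores at shared Cas13b peaks was replaced by the median score of shared and unshared peaks within each list.

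Genes were named by a rule fixed before the data were examined. It took the 8 protein-coding or lncRNA genes with the highest score in each Cas list after removal of peaks near a vector peak, and 10 genes with such a peak in the 3 Cas13 lists without crRNA and none in the Cas9 list, ordered by the worst of their 3 ranks. It also took 8 genes found with crRNA and not without, 8 the other way, the 5 highest of each vector list, and up to 4 members of each fixed list, or all members of a list with at most 6. Positions in the text are those of the highest-scoring peak of the gene in the list named.

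Alternatives kept only peaks with a score at or above the list median, kept only chromosomes 1 to 22, X and Y, used 500 bases or an identical position as the window, shortened the Cas lists by score to the shortest of them, kept peaks near a vector peak or removed them, used the gene as the unit, and left random lists unmatched. In tests on simulated data, planted overlaps of the Cas13b list (10408 peaks) were recovered with a largest gap of 0 percentage points, and 95.5% of lists placed at random fell inside the placement range. Of 200 random lists of 50 genes, 5% fell outside the range for the Cas13b list. Of 200 lists whose genes were drawn with 4 times the weight when they had a peak, 98.5% lay above that range. The outcomes for planted overlaps, placements and random lists were largely fixed by how the data were simulated. They check the calculation and not the choice of window or regions. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.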

Results

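RIP-seq peaks were compared across 7 immunoprecipitations from 293FT cells, a human embryonic kidney line. Cells carried an empty vector, Cas9, a DNA-cutting nuclease, or one of the RNA-cutting effectors Cas13a, Cas13b and Cas13d, each bearing a FLAG tag; Cas13b was also expressed together with a CRISPR RNA labelled crNT. Vector cells were precipitated with IgG and with the FLAG antibody. The title of the series frames the question as RNA binding that is intrinsic to Cas13. Each condition was 1 library, so no difference below has a replicate check, and the depth behind each list is unknown.

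RPL8, which encodes a protein of the large ribosomal subunit, carried peaks in all 5 Cas lists and 1 in the vector FLAG list, and the Cas13 lists were the longest. There were 13976 peaks with Cas13a, 10746 with Cas13b, 16752 with Cas13b and crNT and 8927 with Cas13d, against 4121 with Cas9, 640 with the vector and FLAG antibody and 150 with IgG. Peaks fell in 4646, 4007, 5403 and 3476 genes for the Cas13 lists in that order, in 2048 genes for Cas9, and in 416 and 82 genes for the vector lists. Protein-coding genes held 87.3% to 87.7% of the peaks on assembled chromosomes or the mitochondrial genome in the Cas lists, 79.7% in the vector FLAG list and 59.5% in the IgG list. Genes classed as lncRNA numbered 61 with Cas13a, 33 with Cas13b, 69 with crNT, 30 with Cas13d and 15 with Cas9.

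**Figure D1:**
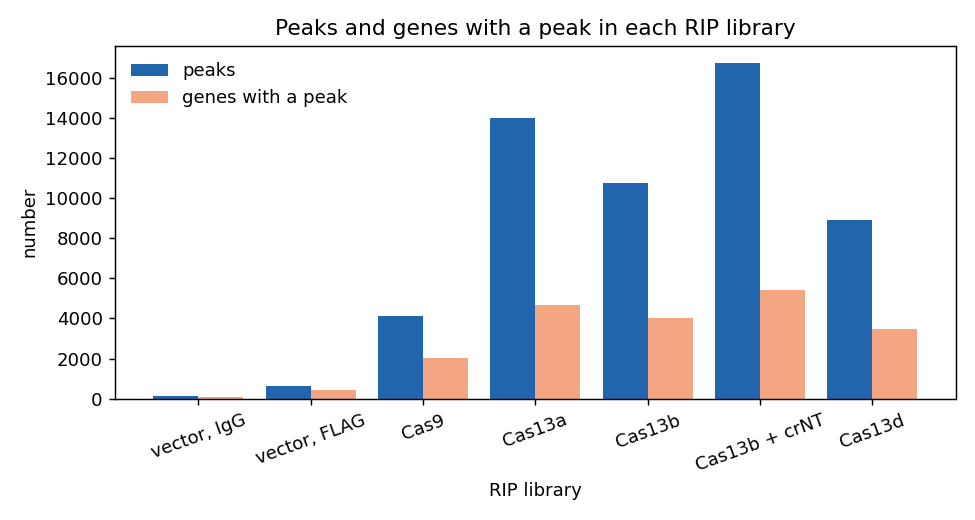
Number of peaks and number of genes with a peak (vertical axis, counts) in each of the 7 RIP libraries (horizontal axis), 1 library per bar. The Cas13 lists run from 8927 to 16752 peaks, the Cas9 list has 4121, and the vector lists have 640 and 150.

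Background sites included small structured RNAs, ribosomal RNA and histone transcripts, beside the protein-coding peaks counted above. RN7SL1 and RN7SL2, the RNA of the signal recognition particle, RN7SK, which restrains transcription elongation, and RPPH1, the RNA of RNase P, had a peak in all 7 lists. The RN7SK peak lay at position 52995746 of chromosome 6 in both vector lists and between 52995740 and 52995747 in the Cas lists. The 45S ribosomal DNA range of chromosome 21 held 21 IgG peaks and 19 vector FLAG peaks, and between 17 and 22 in the Cas lists. These made up 14.0% of the IgG list and at most 0.461% of a Cas list. Of the 5 highest IgG genes, the histone gene H2AC18, the desaturase gene SCD, the ribosomal protein gene RPL13 and the elongation factor gene EEF2 also had a peak in every other list. HFM1, a meiotic helicase gene, had a single peak near position 91387424 of chromosome 1 in both vector lists and in the Cas9, Cas13a and Cas13b lists, and none with crNT or Cas13d.

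Vector FLAG peaks of high score lay in H3C10, a histone gene, SRSF1, a splicing regulator, DBN1, an actin-binding protein of dendrites, and SNRNP70, a component of the U1 particle. SRSF1 had 4 peaks in the vector FLAG list, 1 in the Cas9 list and none in the Cas13 lists. MALAT1, an abundant nuclear lncRNA, had 6 peaks in the vector FLAG list, 2 with Cas13a and none in the other lists. NEAT1, the scaffold of paraspeckles, had 2 with vector FLAG, 2 with Cas9, 5 with Cas13a, 3 with Cas13b and 2 with Cas13d. The mitochondrial ribosomal RNA genes RNR1 and RNR2 carried peaks in both vector lists and in the Cas9 and Cas13a lists, and none in the Cas13b, crNT and Cas13d lists. COX1 and COX3, subunits of cytochrome oxidase encoded in the mitochondrion, had 1 peak each, with Cas13a.

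Each Cas list held between 332 (Cas13a) and 360 (Cas13d) peaks near a vector peak, so the shares below differ mainly with list length. The vector lists hold only 640 and 150 peaks, which limits the share that a long list can reach. The share within 100 bases of a peak in either vector list was 8.37% for Cas9 (95% interval 7.54 to 9.26), 2.38% for Cas13a (2.13 to 2.64), 3.15% for Cas13b (2.82 to 3.49), 2.11% for crNT (1.90 to 2.34) and 4.03% for Cas13d (3.63 to 4.46). In the other direction, 49.7% of the vector FLAG peaks were found in the Cas9 list, 47.2% with Cas13a, 49.1% with Cas13b, 50.9% with crNT and 50.8% with Cas13d. The IgG list recovered between 58.0% and 60.7% of its 150 peaks in each Cas list, and 51.3% in the vector FLAG list. Intervals cover counting error and not the difference between libraries.

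Cas13 lists were set against Cas9 as the comparator that targets DNA. PFN1, an actin monomer binder, HSPBP1, a cofactor of the chaperone HSP70, FAU, which encodes a ribosomal protein fused to a ubiquitin-like domain, and PRELID1, a mitochondrial lipid carrier, had peaks in all 4 Cas13 lists and none with Cas9 or in a vector list. PFN1 had 2 peaks with Cas13a, 2 with Cas13b, 3 with crNT and 2 with Cas13d, the highest at position 4945936 of chromosome 17 in the Cas13a list. HSPBP1 peaks lay at position 55262571 of chromosome 19 with Cas13a, Cas13b and crNT and at 55262580 with Cas13d. ZMIZ2, a transcriptional coregulator, had 8, 7, 9 and 5 peaks with Cas13a, Cas13b, crNT and Cas13d, none with Cas9 and 1 in the vector FLAG list. The rule also named the synaptic scaffold gene DLGAP4, the gene WSCD1, ARPC1A of the actin-nucleating Arp2/3 complex, GNB1, a G protein beta subunit, and TECPR2, linked to autophagy. DLGAP4 had 1 vector FLAG peak, and the others had none in a vector list.

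Peak numbers in the Cas13 lists exceeded the Cas9 list 3.39-fold for Cas13a (95% interval 3.28 to 3.51), 2.61-fold for Cas13b (2.52 to 2.70), 4.07-fold for crNT (3.93 to 4.21) and 2.17-fold for Cas13d (2.09 to 2.25). Gene numbers exceeded it 2.27-, 1.96-, 2.64- and 1.70-fold. After removal of peaks near a vector peak, 1896 of the 1935 Cas9 genes, 98.0%, had a peak in at least 1 Cas13 list, and 39 had none. Of the 6539 genes in any Cas list only these 39 lay outside the 4 Cas13 lists, so the 98.0% largely follows from their pooled length. Single lists shared 1734 (Cas13a), 1729 (Cas13b), 1829 (crNT) and 1667 (Cas13d) genes with Cas9. Independent lists drawn from the 6539 genes would share 1351, 1164, 1578 and 1002. Genes in all 4 Cas13 lists numbered 2390, of which 1499 were also in the Cas9 list and 891 were not. With the Cas lists shortened by score to the 4121 peaks of Cas9, an alternative chosen after seeing the data, gene numbers were 2047, 2024, 2020 and 1960 against 2048. The fold differences compare libraries of unknown depth.

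Several genes led more than 1 Cas list. In the Cas9 list, peaks of high score lay in RPL8, EEF2, the actin gene ACTB, ZNF768, a zinc finger gene, the cell cycle transcription factor gene MYBL2, TK1, which encodes thymidine kinase, and RPS2 of the small ribosomal subunit. MYBL2 had 3 peaks with Cas9, 11 with Cas13a, 10 with Cas13b, 11 with crNT and 12 with Cas13d. The Cas13a list was led by RPL8, the ribosomal protein genes RPS3, RPSA and RPL13, the glycolytic gene PKM, LMNB2 of the nuclear lamina, SH3GL1, an endocytic adaptor, and SORBS3, a focal adhesion adaptor. RPS3 had 5 peaks with Cas13a, 3 with Cas13b, 3 with crNT and none with Cas9 or Cas13d. PKM had 4 peaks with Cas9, 8 with Cas13a, 8 with Cas13b, 7 with crNT and 5 with Cas13d, and none in the vector lists.

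The Cas13b list was led by HMGA1, an architectural chromatin protein gene, the histone genes H2AC20 and H4C4, RPL8, ZYX, which encodes the focal adhesion protein zyxin, PKM, SH3GL1 and RPS2. With crNT the leading genes were RPL8, H4C4, ZYX, the glycolytic gene GAPDH, the repressor gene ERF, CDC42EP1, an effector of the GTPase CDC42, the linker histone gene H1-4 and HCFC1, a transcriptional cofactor. HCFC1 carried 14 peaks with Cas9, 18 with Cas13a, 16 with Cas13b, 18 with crNT and 15 with Cas13d, against 3 in the vector FLAG list. The Cas13d list was led by FKBP8, an immunophilin of the mitochondrial membrane, EPN1, an endocytic adaptor, COX8A, a cytochrome oxidase subunit, CDT1, a replication licensing factor, RPL8, ERF, ESS2, a splicing-associated gene, and RPL28. The ERF peak lay at position 42249161 of chromosome 19 with Cas13a, Cas13b and Cas13d and at 42249162 with crNT.

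Positions recurred between Cas lists. After removal of peaks near a vector peak, the share of the shorter list found in the longer within 100 bases had a median of 52.5% over the 10 pairs. It was lowest, 44.6% (95% interval 43.5 to 45.6), for Cas13d in Cas13b and highest, 58.3% (57.4 to 59.3), for Cas13b in crNT. Cas9 peaks were found at 52.8% with Cas13a, 52.1% with Cas13b, 57.2% with crNT and 52.9% with Cas13d. Placement of the peaks at random within the merged peak regions of the same genes gave medians between 37.3% and 54.5%, and in 9 of the 10 pairs the share of gene-assigned peaks lay above each of 1000 placements. The exception was Cas13a in crNT, at 49.5% beside a median of 49.0% and a range of 48.1 to 49.7. Relative to the medians in merged regions, the observed share was 1.01 to 1.38 times as high. Placement over whole gene spans reached at most 6.0% in any of the 10 pairs. Spans include introns and peaks gathered toward gene ends, so that low value is little evidence that positions recur. Of 29257 distinct sites, 16640 lay in 1 Cas list and 1143 in all 5.

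**Figure D2:**
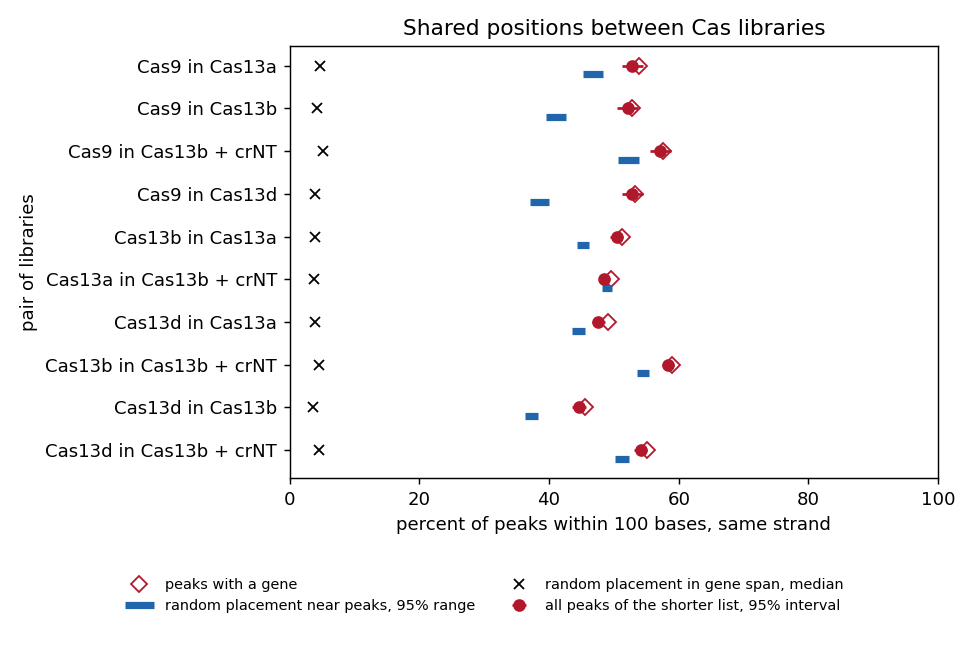
Percent of peaks (horizontal axis) of the shorter list found in the longer list on the same strand within 100 bases, for the 10 pairs of Cas libraries (vertical axis). Circles are all peaks with exact 95% binomial intervals, diamonds are peaks with a gene, blue bars are the 95% range of random placements in merged peak regions and crosses are medians of placement over whole gene spans; circles lie between 44.6% and 58.3%.

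The crNT list was compared with the list of Cas13b alone, the pair that differs by the presence of a crRNA. PVT1, a lncRNA next to MYC, had 2 peaks with crNT, the higher at position 128100978 of chromosome 8, and none in the other 6 lists. TPT1, which encodes a translationally controlled tumour protein, CHCHD10 and ROMO1 of mitochondria, FBXO42, a ubiquitin ligase subunit, H2BC8, a histone gene, SLC39A4, a zinc importer, and CXCL16, a chemokine, were also found with crNT and not with Cas13b alone. Apart from PVT1, each of these 8 genes had a peak with Cas13a. In the other direction, CDKN2A, which encodes cell cycle inhibitors, NCAPD3 of condensin II, the ribosomal protein gene RPL31 and CDC123 had peaks with Cas13a and Cas13b and none with crNT, Cas13d or Cas9. RPL3L, UQCC4 and CDK5RAP3 had peaks in the Cas13b list and in no other, and TRIM2, a ubiquitin ligase, had peaks with Cas13a, Cas13b and Cas13d.

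Peaks with crNT exceeded those with Cas13b alone 1.56-fold (95% interval 1.52 to 1.60). After removal of peaks near a vector peak, 6069 positions were shared, 58.3% of the Cas13b list (57.4 to 59.3) and 37.0% of the crNT list (36.3 to 37.8). Genes were shared more often, at 3600 of 3932 for Cas13b and 67.5% of 5331 for crNT, with 332 and 1731 found in 1 list alone; independent lists of these sizes, drawn from the 6539 genes in any Cas list, would share 3206. Shared peaks had a median score of 11 in the Cas13b list, beside 7 for unshared peaks, and of 16 in the crNT list, beside 9. With each list split by score into 4 equal groups, 78.0% of Cas13b peaks were shared in the highest group and 38.0% in the lowest. The corresponding values with crNT were 69.2% and 14.5%. Without a second library of either kind, the spread of these shares is unknown.

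Peaks gathered toward the end of protein-coding genes. With each gene span cut into 10 equal parts in the direction of transcription, the last part held 36.5% of peaks for Cas9 (95% interval 34.9 to 38.1), 34.4% for Cas13a (33.6 to 35.3), 35.9% for Cas13b (34.9 to 36.9), 32.2% for crNT (31.5 to 33.0) and 35.0% for Cas13d (34.0 to 36.1). It held 19.9% in the vector FLAG list (16.4 to 23.8) and 32.0% in the IgG list (21.7 to 43.8); with scores at or above the median the IgG share was 20%. The first part held 17.4% of vector FLAG peaks (14.1 to 21.1), 16% of IgG peaks (8.55 to 26.3), 7.61% for Cas9 (6.74 to 8.54), 3.10% for Cas13a (2.79 to 3.43), 4.63% for Cas13b (4.21 to 5.09), 6.17% for crNT (5.78 to 6.58) and 6.57% for Cas13d (6.02 to 7.16). SRSF1 is an example of the first kind: its highest vector FLAG peak lay at position 58007125 of chromosome 17, in a span from 57989038 to 58007246. In GAPDH, which spans positions 6534517 to 6538371 of chromosome 12, the highest peak lay at 6538173 with Cas9, Cas13a, Cas13b and crNT and at 6538174 with Cas13d. Spans include introns, so a part of a span is not the same part of the mature transcript.

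**Figure D3:**
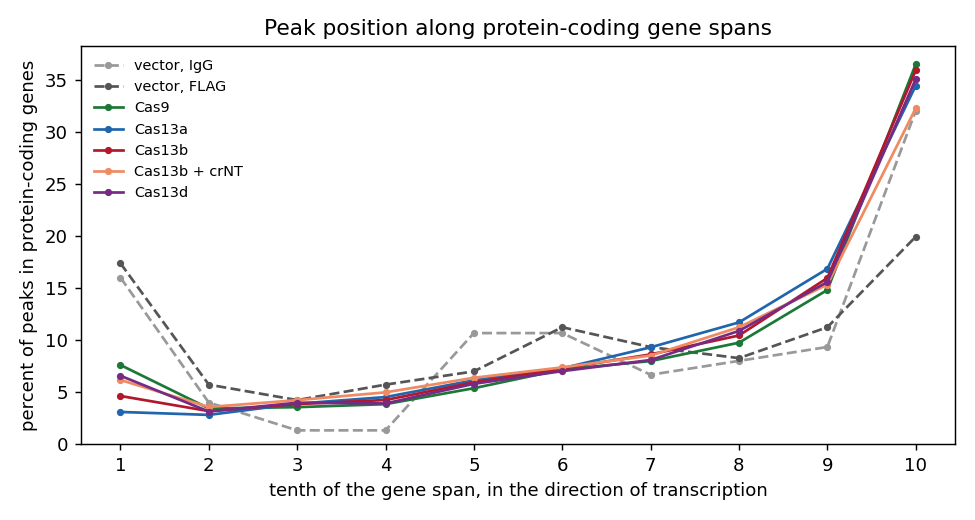
Percent of peaks in protein-coding genes (vertical axis) by part of the gene span, cut into 10 equal parts in the direction of transcription (horizontal axis), 1 line per RIP library, dashed for the vector libraries. The last part holds 32.2% to 36.5% of the peaks in the Cas lists and 19.9% in the vector FLAG list, and the first part holds 17.4% in the vector FLAG list and 3.10% to 7.61% in the Cas lists.

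Histone genes were above the random range in all 7 lists, the vector lists included. Here and below, counts are out of the members with a peak in any of the 7 lists, for histones 50 of 69 genes. Replication-dependent histone genes, whose transcripts end in a stem-loop, had a peak in 39 of 50 members with Cas9 beside a random median of 19, in 48 with Cas13a beside 36, in 47 with Cas13b beside 33, in 50 with crNT beside 44 and in 43 with Cas13d beside 29. The vector FLAG list held 26 beside 5, and the IgG list 7 beside 2. Without peaks near a vector peak no Cas list was above the range, and the Cas13a, Cas13b and crNT lists were below it. The removal falls more on histones: 26 of the 50 had a vector FLAG peak, against 416 of the 6637 genes. The fall below the range partly follows from the removal and does not show depletion. The crNT value was inside the range with scores at or above the median, and the Cas13d value at equal length. H4C14 and H4C15 had their highest peaks at positions 149832840 and 149860977 of chromosome 1 with crNT, and the near-identical copies leave the member uncertain. Cytosolic ribosomal protein genes had a peak in 32 of 57 members with Cas9 (random range 14 to 27), 54 with Cas13a (34 to 47) and 52 with Cas13b (30 to 44), and in 50 with crNT (44 to 54) and 30 with Cas13d (25 to 40), both inside the range. The IgG list was above its range too, with 6 members (0 to 4), and vector FLAG was inside it with 9. RPL36 had 1 peak with Cas9 and 2 in each Cas13 list. The Cas9 value fell inside the range when the lists were of equal length, and the Cas13a and Cas13b values did not. The Cas9 list is the shortest Cas list, so equal length leaves its peaks unchanged. Its call moved there only because the random range moved, and the same holds for Cas9 at equal length below.

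Cytoskeleton genes had a peak in 22 of 22 members with Cas13a beside a random median of 16, in 19 with Cas13b beside 13, in 17 with Cas13d beside 12 and in 13 with Cas9 beside 7, each above the range, and in 21 with crNT, inside it. The vector FLAG list was also above its range, with 5 members (0 to 4), and at equal length the crNT value was above its range. ACTG1, the gamma actin gene, had peaks in all 7 lists, as did CFL1, which encodes the actin-severing protein cofilin. Translation factor genes had a peak in 25 of 25 members with Cas13a (13 to 22) and 21 with Cas13b (11 to 20), above the range, and in 23 with crNT, 16 with Cas13d and 11 with Cas9, inside it. EEF1G, an elongation factor subunit, had 7 peaks each with Cas13a, Cas13b and crNT, 3 with Cas13d and 1 with Cas9. EIF3L, an initiation factor subunit, had 2 with Cas13a, 1 with Cas13b, 1 with crNT and none with Cas13d or Cas9. Calls for cytoskeleton in the Cas9, Cas13b and Cas13d lists, and for translation factors, were lost under at least 1 alternative.

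Of 477 zinc finger genes, 133 had a peak in any list, some of them with crNT alone. Of these 133, 127 had a peak with crNT, above a random range of 102 to 118. The Cas13a list held 86, Cas13b 83, Cas13d 65 and Cas9 44, each inside its range. ZNF777 had 5 peaks with crNT, 4 with Cas13a, 3 with Cas13b, 4 with Cas13d and 1 with Cas9. ZNF598, a sensor of collided ribosomes, and ZNF408 were the other leading members beside ZNF768. The crNT value fell inside the range when peaks under the median score were left out and when lists were of equal length. Mitochondrial ribosomal protein genes stayed inside the range in all 5 Cas lists, with 16 of 51 for Cas9, 35 for Cas13a, 34 for Cas13b, 48 for crNT and 26 for Cas13d. MRPL4, MRPS34, MRPL10 and MRPL38 each had a peak in all 5 Cas lists and none in the vector lists. The vector FLAG list held 0 of the 51 members, below its range of 1 to 8, and was inside the range with scores at or above the median and without matching on span. Under that last setting, and without peaks near a vector peak, the crNT value was above the range.

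Glycolysis genes had a peak in 10 of 13 members with Cas9, above a random range of 1 to 8, and in 10, 10, 12 and 9 with Cas13a, Cas13b, crNT and Cas13d, inside the range. The IgG list was above its range as well, with 4 members (0 to 1). With scores at or above the median both values were inside the range. At equal length, which leaves the Cas9 peaks unchanged and moves the random range, the Cas9 value was too. ENO1, which encodes enolase, had peaks in all 7 lists, and TPI1, which encodes triosephosphate isomerase, had 2 with Cas13a, 2 with Cas13b, 1 with crNT, 2 with Cas13d, 1 with IgG and none with Cas9. Chaperone genes had a peak in 6 of 16 members with Cas9, 13 with Cas13a, 12 with Cas13b, 13 with crNT and 10 with Cas13d, all inside the range. P4HB, a disulfide isomerase, and HSPA1A, an inducible HSP70, had peaks in all 5 Cas lists, and CCT7 and CCT5 of the chaperonin had none with Cas9. Proliferation genes were inside the range in each Cas list, with 8 of 16 for Cas9 and 11, 13, 14 and 9 for the Cas13 lists. MCM7, MCM5, MCM2 and MCM4, subunits of the replicative helicase, had peaks in all 5 Cas lists. Splicing factor and hnRNP genes were inside the range too, with 11 of 25 for Cas9 and 18, 17, 18 and 12 for the Cas13 lists, and 7 in the vector FLAG list, above its range of 0 to 4. HNRNPUL1 had 3 peaks with Cas9, 9 with Cas13a, 9 with Cas13b, 13 with crNT and 5 with Cas13d; SRSF4, HNRNPU and the nucleolin gene NCL were the other leading members.

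Genes of double-stranded RNA sensing and the interferon response had a peak in 2 of 8 members with Cas9, 3 with Cas13a, 6 with Cas13b, 8 with crNT and 4 with Cas13d, each inside the range. ADAR, which edits double-stranded RNA, had 5 peaks with Cas13a, 2 with Cas13b, 3 with crNT and none with Cas9 or Cas13d. MAVS, an adaptor of RNA sensing, and the stress gene ATF4 had peaks in all 5 Cas lists, and ATF3 had 1 each with Cas13b, crNT and Cas13d. Small structured RNAs had a peak in 9 of 13 members with Cas9, 9 with vector FLAG and 5 with IgG, above the range, and in 10, 10, 11 and 10 in the Cas13 lists, inside it. The Cas9 value was inside the range with scores at or above the median and without peaks near a vector peak. It was also inside at equal length, where its peaks are unchanged and only the random range moves. Without peaks near a vector peak the Cas13a, Cas13b and crNT values were below the range. As 9 of the 13 had a vector FLAG peak, this partly follows from the removal. Mitochondrially encoded genes had a peak in 0 of 4 members with Cas13b and with crNT, below the range, and in 0 with Cas13d, 2 with Cas9, 2 with vector FLAG and 4 with Cas13a, inside it. The IgG list was above its range, with 2 members (0 to 1). At equal length the Cas13b and crNT values were inside the range, and the Cas13b value was inside it without matching on span. Nuclear-retained and abundant lncRNAs had a peak in 2 of 5 members with crNT, below the range of 3 to 5, and in 4 with Cas13a, 2 with Cas13b, 1 with Cas13d and 1 with Cas9. The crNT value was inside the range at equal length, without peaks near a vector peak and without matching on span. SNHG1, a snoRNA host, had 1 peak each with Cas13a, Cas13b and crNT, and GAS5 had 1 with Cas13a.

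Among human sequences carried by lentiviral plasmids, EEF1A1 had 1 peak each with vector FLAG, Cas13a and Cas13d, and RNU6-1 and PGK1 had none. Peaks were assigned to genes without regard to strand. The EEF1A1 peaks with vector FLAG and Cas13a lay on the plus read strand and the Cas13d peak on the minus. The Cas13d peak thus points to RNA of the opposite strand and not to the EEF1A1 transcript. Of 20 markers of tissues other than kidney epithelium, 3 had a peak in any list. MBP and GFAP had 1 each with Cas13a, and COL1A1 had 1 each with Cas13b and Cas13d. With crNT both of these lists held 0 of their 2 and 3 members with a peak in any list, below the range, and both were inside it with scores at or above the median and at equal length. The value for plasmid-borne sequences was also inside it without peaks near a vector peak and without matching on span. Among the vector lists, the IgG values for histones and mitochondrially encoded genes and the vector FLAG value for cytoskeleton were inside the range with scores at or above the median. At equal length of the Cas lists, so were the IgG values for histones and cytosolic ribosomal proteins and the vector FLAG value for cytoskeleton. The vector lists are not shortened in that setting, so these calls moved with the random range. Of the 80 combinations of a fixed list and a Cas list, 17 lay above the random range and 5 below. At most 4 would be expected outside by chance if lists were independent. Abundance of the RNA was not matched, so calls above the range do not tell a preference of a Cas protein from abundant RNA.

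**Figure D4:**
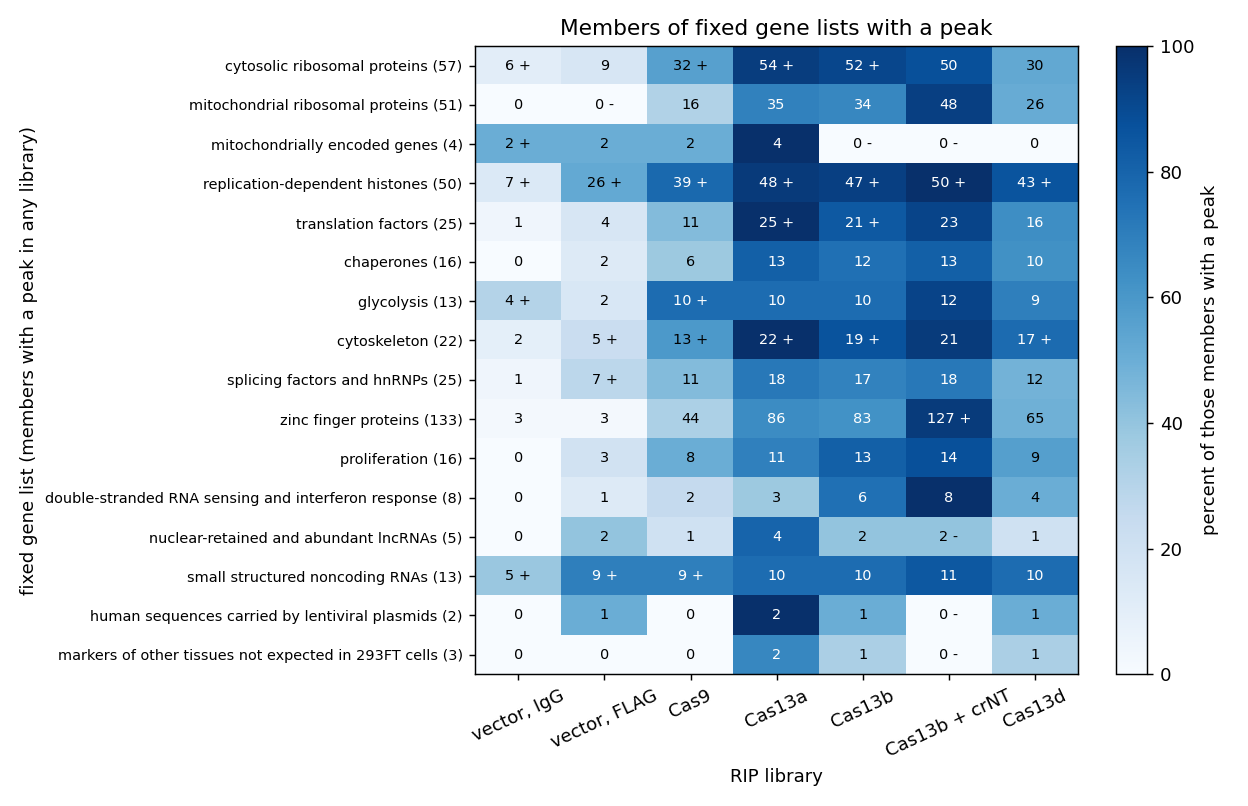
Members of the 16 fixed gene lists (vertical axis, with the number that have a peak in any library) with a peak in each RIP library (horizontal axis). Numbers are members with a peak, colour is their percent, and + or - marks a count above or below the 95% range of 10000 random lists; histones are above it in all 7 libraries.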

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

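The identical position, the equal length for genes, gene lists and position along the span, and placement over whole gene spans were chosen after seeing the data; the other alternatives were fixed before. No paired analysis was possible because each group is 1 library and no result comes from a test. Reciprocal overlap, assignment by peak length, the order of transcript regions and base composition were not run, since peaks are positions and no exons or sequence were used; a score threshold common to the lists was not used, since scores are not compared between lists. With the score at or above the list median, a setting that shortens each list by construction, peaks numbered 78 (IgG), 354 (vector FLAG), 2187 (Cas9), 7492 (Cas13a), 6355 (Cas13b), 8543 (crNT) and 5080 (Cas13d). Genes then numbered 31, 237, 1233, 3095, 3445 and 2265 for IgG, vector FLAG, Cas9, Cas13a, crNT and Cas13d. The ratio to Cas9 became 2.91 for Cas13b, 3.91 for crNT and 2.32 for Cas13d, and each Cas13 list stayed longer than the Cas9 list. At equal length, genes numbered 2047 (Cas13a), 2024 (Cas13b), 2020 (crNT) and 1960 (Cas13d), so the larger gene numbers of the Cas13 lists rest on their length. The share of peaks near a vector peak within 500 bases was 10.6% (Cas9), 3.28% (Cas13a), 4.27% (Cas13b), 2.90% (crNT) and 5.51% (Cas13d); at an identical position it was 0.340%, 0.136%, 0.149%, 0.113% and 0.134%. With scores at or above the median it was 9.47% for Cas9. The median overlap of the 10 pairs was 71.7% within 500 bases, 2.11% at an identical position, 39.3% at equal length, 54.3% with peaks near a vector peak kept, 55.1% with scores at or above the median and 87.7% with the gene as the unit. The share of Cas13b peaks found with crNT was 76.0% within 500 bases, 2.57% at an identical position, 51.7% at equal length and 91.6% by gene. The share of crNT peaks found with Cas13b alone was 48.4%, 1.63%, 51.7% and 67.5% under the same settings, 37.9% with peaks near a vector peak kept and 43.1% with scores at or above the median. In the last of 10 equal parts of the span, scores at or above the median gave 20% (IgG), 34.7% (Cas9) and 36.1% (Cas13a), and equal length gave 37.2% (Cas13a), 37.5% (Cas13b) and 34.9% (crNT). In the first part, scores at or above the median gave 22.1% (vector FLAG), 2.51% (Cas13a), 5.23% (crNT) and 6.0% (Cas13d), and equal length gave 2.35% (Cas13a), 4.09% (Cas13b), 4.37% (crNT) and 5.63% (Cas13d). Combinations of a gene list and a Cas list above the random range fell from 17 to 10 with scores at or above the median, with peaks near a vector peak removed (9 shared with the 17) and at equal length (9 shared). Combinations below it numbered 3 with scores at or above the median, 3 on chromosomes 1 to 22, X and Y, 9 with peaks near a vector peak removed (3 shared with the 5, and histones and small structured RNAs in the Cas13a, Cas13b and crNT lists), 0 at equal length and 2 without matching on span. For the named genes, the number of Cas lists with a peak was the same within 1.5 times in 405 of 456 alternatives and lower in the other 51. For single pairs 51 of 70 alternatives lay outside the interval. Apart from list length by construction, the cause of these shifts was not tested, and unknown depth limits each comparison of list lengths.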

Other observations

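The loci in this paragraph were chosen after their values were seen. Upstream of EEF1A1, an elongation factor gene whose promoter is used in expression plasmids, plus-strand peaks lay 117 bases beyond the gene's end on chromosome 6 with Cas9, 124 with Cas13a, 95 with Cas13b and 120 with crNT. The crNT list also had a minus-strand peak there, 47 bases beyond the end. Neither vector list nor the Cas13d list had a peak within 1000 bases outside the gene. Peaks on both strands within 100 bases of each other were few: 2 pairs with Cas9, 5 with Cas13a, 2 with Cas13b, 9 with crNT, 2 with Cas13d and 0 in the vector lists. A pair where the genes BUD31 and PTCD1 overlap, at position 99419378 of chromosome 7 with Cas9, recurred in the Cas13b, crNT and Cas13d lists. In protein-coding genes with 2 or more peaks, all peaks lay on 1 strand in 99.3% to 99.7% of genes of the Cas lists.

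The tests of vector background and of strand below were chosen after the results were seen; those at equal length and of zinc finger genes were set before their values were computed. The first pattern is the length of the Cas13 lists beside the Cas9 list. The 640 strongest peaks of each Cas13 list were set beside the vector FLAG peaks. Vector background seen at greater depth would put as large a share of them in the first of 10 equal parts of gene spans. That part held 17.4% of vector FLAG peaks (95% interval 14.1 to 21.1) and at most 4.32% of these Cas13 peaks, with Cas13d (2.76 to 6.42). For the strongest Cas13 peaks, this argues against vector background as the whole source. The weaker peaks of these lists were not part of the test. Cas9 peaks were also below the vector FLAG share, at 7.61%. The test therefore does not tell why the Cas13 lists are longer than the Cas9 list. An earlier test, the share of the strongest peaks near a vector FLAG peak (16.4% to 20.3%), was set aside because the share of vector FLAG peaks in each Cas13 list, 47.2% to 50.9%, capped it near the bound set for it and left the outcome almost fixed. The prediction set for depth or threshold alone was that lists of equal length would overlap alike. Cas9 overlapped Cas13 lists by at most 37.9%, below the lowest value between Cas13 lists, 38.3%, but with overlapping intervals. This comparison cannot decide, because the Cas9 list kept its weak peaks while each Cas13 list kept only its strongest. Weak peaks can be shared less often: 38.0% of Cas13b peaks were shared with crNT in the lowest score group and 78.0% in the highest. Depth, threshold and a difference between the proteins cannot be told apart with 1 library each and no read totals.

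The second pattern is the longer Cas13b list with crNT. List length alone may account for its zinc finger genes: with the crNT list shortened by score to the length of the other, 80 of 133 members had a peak, beside 83 with Cas13b alone. The shortened list also held 4043 genes, beside 4007. What made the list longer stays open, because an effect of the crRNA and the depth of the library are confounded, and neither was tested.

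The third pattern is an excess of plus-strand peaks with Cas13a, 56.5% (55.7 to 57.3), where the other 4 Cas lists had 48.8% to 49.6%. Among peaks scored under the list median the plus share was 65.3%, and at or above the median it was 48.9% (47.8 to 50.1). More binding to transcripts of one genome strand would raise both shares, and the second argues against it. An excess among weak peaks is consistent with a lower effective threshold on plus-strand reads, which were called separately, as a hypothesis formed on the same data. No biological explanation of this pattern was tested beyond that.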
